A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

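The data are 2-colour ChIP-chip profiles of Saccharomyces cerevisiae. Per the labels, factors carried a C-terminal myc or HA tag at their own locus, immunoprecipitate and whole-cell extract DNA were amplified by linker-mediated PCR, labelled with Cy5 and Cy3 by Klenow incorporation and hybridised together to arrays of spotted open reading frames. Dyes were reversed in at least 1 replicate, scans were made on a GenePix 4000B and replicates were combined in Rosetta Resolver, per the labels' protocols and the series design text. The unit of the deposited values is a log2 ratio of the 2 channels per probe. Its direction, the way replicates were combined and any normalisation within arrays are not given in the sources used here. Values stop at plus and minus 6.64, the log2 of a 100-fold ratio, in 18 of 24 columns, and no column goes beyond.

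Direction was examined on the values. Strongly transcribed genes are positive in most columns, which makes immunoprecipitate over extract likely. In 3 pairs of columns the Pearson correlation over all probes was below -0.3: the Mud2 profile with 6-azauracil (-0.34), spt5_194 with Mud2 plus RNase (-0.36), and Mud2 plus RNase with Lea1 in SUB2 wild type (-0.32). The last 2 had Spearman correlations of 0.05 and 0.03, the first -0.41. Over all genes their rank correlation with RNA polymerase II was 0.14 for the Mud2 profile, 0.27 for 6-azauracil, 0.37 for spt5_194, 0.08 for Lea1 and 0.01 for Mud2 plus RNase. Over intron genes the rank correlation was 0.66 for the Mud2 profile with Mud2 without RNase. It was 0.63 for Lea1 in SUB2 wild type with the Lea1 profile, and 0.77 for spt5_194 with its control. Glycolytic genes had a median of 1.345 with 6-azauracil. These values argue against a turned sign for these columns, although the Mud2 profile and 6-azauracil ran against each other. Mud2 plus RNase had little pattern to judge by. The 5 columns were used as deposited. Results with a turned sign were computed for excesses, differences, changes, counts, correlations, the contrast and lists that were apart, and not for single genes.

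Each column is a group of its own, because its biological replicates are already combined: 17 columns pool 3, RNA polymerase II pools 2, 4 replicates each stand behind BBP, Prp5, Spt5 and the Prp40-3myc control, 5 behind Prp40-9myc and 6 behind Sub2, per the labels. Values of single replicates were not analysed here, so no replicate could be left out in turn and no test between samples was made. The array holds 6284 probes, of which 5707 matched a locus of the RefSeq gene table for assembly R64. Leaving out 16 mitochondrial probes and those that are not genes gave 5674 genes, and 610 probes were not used. The RefSeq table served for names, neighbours and gene spans. It gives no exons, so intron genes come from a list written from memory before the data were examined. It names 228 genes, of which 213 were measured, 91 for ribosomal proteins and 122 others. RPL22B, RPL29, RPL36B and RPS14A are among those without a usable probe. A further 46 genes were placed in neither class, which leaves 5415 intronless genes, 40 of them for ribosomal proteins. Medians over all probes ranged from -0.17 for Mud2 to 0.05 for Prp19, and robust SDs over genes from 0.09 to 0.69. Arrays carry no count or depth, and their small number limits precision.

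Intron excess is the median log2 ratio of intron genes minus the median over 10000 random lists of intronless genes of equal size, drawn with replacement within 20 quantile bins of the RNA polymerase II column. The polymerase column itself was compared with unmatched lists. The percentile of the observed median among those lists describes its position, and below 2.5 or above 97.5 it was called apart. It is not a p-value, since genes are not independent replicates. Ribosomal protein genes with and without an intron were compared by the difference of medians and its percentile among relabelled lists. Changes are treated minus control per gene, with the same lists. Correlations are Spearman's rho across genes. The early minus late contrast used 211 genes with values in 6 columns. Other lists, also fixed beforehand, cover meiotic intron genes, snoRNA host genes, glycolysis, translation factors and chaperones, heat shock, histones, galactose use, nucleotide synthesis and amino acid synthesis.

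Named genes followed a rule fixed before the data were examined, like the comparisons, lists and the first set of alternatives. It takes the 3 highest genes of each profile, 10 intron genes at each end of the contrast among those whose mean passes the 95th percentile of intronless genes, and 5 intron and 2 intronless genes at each end of every change, with a control value above its 75th percentile for falls. List members, ACT1, YRA1, DBP2, GCR1 and the genes of tagged factors may also be named. Values at the limit were left out of these rankings, and 1 gene that the rule takes is not reported here. CBC2 falls outside the rule, as do the Prp2 value of GPI15 and examples of intron genes for Prp40, and they were chosen after their values were seen.

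Alternatives were no matching, matching on Spt5 or on the control column, 10 bins, means, leaving out ribosomal protein genes or neighbours of intron genes (401 intronless genes), genes with a value in every column (5630), quantile normalisation, a 95th percentile threshold, Pearson correlation, a common spread, and leaving out each factor of the contrast. After the data were seen, 4 more kinds were added: leaving out values at the limit, intron genes whose span is not a multiple of 3 (131 genes), a turned sign, and quantile normalisation of the ribosomal protein comparison. The alternatives for changes outside the ribosomal protein group were also added then, and lists were turned only where their change was apart. The procedure was tested on simulated data, with 200 lists of intronless genes per comparison and 1000 random lists each. With no shift 4% of lists were called apart for Prp40, 5.5% for Brr2 and for Sub2, and 6.5% for spt5_194. An added shift of 0.1 was called in 99.5%, 99%, 61.5% and 100% of lists, in the same order. For relabelled ribosomal protein genes in the Prp40 profile 5% were called with no shift and 100% with 0.5. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.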

Results

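Chromatin immunoprecipitation followed by microarray hybridisation (ChIP-chip) measured where spliceosome proteins, an elongation factor and RNA polymerase II sat on the genome of budding yeast. Each of the 24 columns of values stands for 1 tagged factor in 1 strain and culture, and holds 1 log2 ratio per spotted open reading frame, in all likelihood immunoprecipitate over whole-cell extract. There were 12 profiles of unperturbed cells. The other 12 columns held 5 mutant or treated strains with Prp40 or Mud2 and 3 controls, and the Sub2 experiment on Lea1 and Brr2 with 2 mutant and 2 wild-type columns. Biological replicates, from 2 for RNA polymerase II to 6 for Sub2, had been combined into a single column per group. No spread between replicates could be computed, so no p-value is given and every percentile below is a description of 1 column, set against random lists of genes. The small number of arrays limits the precision of every value. Among 5674 genes used, 213 have an intron in the list fixed beforehand, and 91 of these code for ribosomal proteins. Intron excess means the median log2 ratio of intron genes minus that of intronless genes with similar RNA polymerase II values. Column medians over genes lay between -0.14 and 0.05.

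The first comparison asked where each splicing factor sat relative to intron genes. Prp40, a protein of the U1 snRNP that meets the 5' splice site, had a median log2 ratio of 2.14 over 91 ribosomal protein genes with an intron and 0.72 over 40 without one. Its 3 highest genes all carry introns and code for ribosomal proteins, with RPS13 at 2.86, RPS26A at 2.76 and RPL20A at 2.68. Among other intron genes the cell wall gene ECM33 reached 2.23, the translation elongation factor gene EFB1 2.02, the ubiquitin-conjugating enzyme gene UBC4 1.91 and the profilin gene PFY1 1.79. Actin, ACT1, stood at 1.49. Meiotic genes with an intron, which vegetative cells keep nearly silent, had a Prp40 median of -0.09. Within the ribosomal protein group, RPL43B at -0.32 and RPS30A at -0.11 were the 2 intron genes below zero for Prp40.

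Intron excess of the early factors was 1.28 for Prp40, 0.42 for the branch point binding protein BBP and 1.76 for Mud2, its partner at the branch point. The U2 snRNP proteins Lea1 and Prp11 gave 1.08 and 0.38. Prp5, the ATPase that helps the U2 snRNP join, gave 0.45. The ATPase Prp2 and the Prp19 complex ready the spliceosome for catalysis, and both had an excess of 0.47, which for Prp2 was 0.26 when matched on Spt5. Each of these 8 medians lay above all 10000 random lists of intronless genes. Such an excess is not by itself particular to introns, since Spt5, no splicing factor, had 0.57. Intronless glycolytic genes exceeded matched genes by more than intron genes did for Prp2 (0.94), Prp5 (0.66) and Prp11 (0.47). For Prp40, BBP, Mud2, Lea1 and Prp19 they exceeded them by less, with 0.64, 0.33, 0.56, 0.70 and 0.34 in that order. Intron genes that code for no ribosomal protein showed a smaller excess than all intron genes together. It was 0.71 for Prp40, 0.66 for Mud2, 0.55 for Lea1, 0.23 for Prp19 and 0.22 for Prp5. Prp2 had 0.20, and BBP and Prp11 had 0.19 each, and all these values were again above every random list. Only for Prp40 and Mud2 was the excess of these genes above that of glycolytic genes. A mean in place of the median put the Prp2 value at 0.13, inside the range of random lists at percentile 97.0. With quantile normalised columns the Mud2 excess was 0.62, that of Prp11 0.70 and that of BBP 0.74, and outside the ribosomal protein group Mud2 had 0.25, BBP 0.28, Prp11 0.34 and Prp5 0.32. Turning the sign of the Mud2 column, whose direction the labels leave open, turns its excess to -1.76, and to -0.66 outside the ribosomal protein group.

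Ribosomal protein genes with an intron exceeded those without by 1.59 for Mud2, 1.42 for Prp40, 1.06 for Lea1, 0.67 for BBP, 0.64 for Prp11, 0.56 for Prp19, 0.50 for Prp5 and 0.37 for Prp2. The Mud2 difference is -1.59 with the sign of its column turned. The percentile of these differences among relabelled ribosomal protein genes was 100, or 99.9 for Prp2. RNA polymerase II itself went the other way, with 0.89 over ribosomal protein intron genes and 1.18 over intronless ones, a difference of -0.29 at percentile 0.01. Spt5, an elongation factor that travels with the polymerase, had 1.49 and 1.59, a difference of -0.10 at percentile 7.96. After quantile normalisation the difference was 1.06 for BBP, 0.73 for Mud2, 0.67 for Lea1 and -0.16 for RNA polymerase II.

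**Figure D1:**
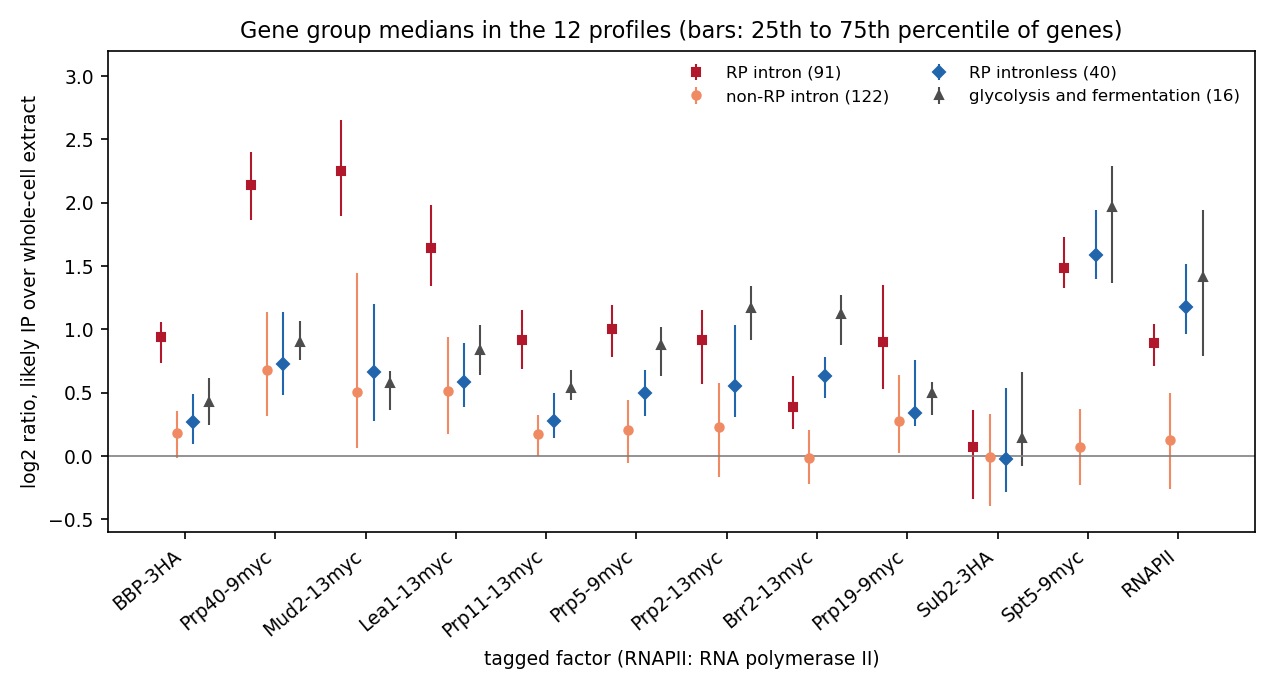
Median log2 ratio (vertical axis) of 4 gene groups in the 12 profiles of unperturbed cells (horizontal axis), with bars from the 25th to the 75th percentile of genes. Ribosomal protein (RP) intron genes lie above intronless ones for Prp40 (2.14 against 0.72) and below them for Brr2 (0.39 against 0.63).

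Brr2, the U5 snRNP helicase that unwinds U4 from U6, had an excess of 0.10 over all intron genes, and -0.02 at percentile 26.3 over those outside the ribosomal protein group. Its median was 0.39 over ribosomal protein intron genes and 0.63 over intronless ones, a difference of -0.24 at percentile 0.22. The highest Brr2 medians among the fixed lists lay on intronless glycolytic genes, at 1.12 over 16 genes, with FBA1 at 1.52, PDC1 at 1.44 and TDH3 at 1.39. Matching on Spt5 in place of RNA polymerase II, or leaving out ribosomal protein genes, ended the overall Brr2 excess, at -0.02 in both cases. Its mean-based value was 0.07, at percentile 89.8, and without matching it was 0.21.

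Sub2, an RNA helicase of the DEAD-box family with roles in splicing and mRNA export, had an intron excess of 0.02 at percentile 63.8, and ribosomal protein intron genes stood at 0.07. None of its intron genes exceeded the 99th percentile of its intronless genes. Its 3 highest genes were AMD1 (AMP deaminase) at 3.21, NUP159 (a nuclear pore protein) at 2.71 and MON2 at 2.59, all intronless. The list of intronless translation factors and chaperones was high for Sub2, with a median of 0.47 at percentile 99.3, led by EFT1 (elongation factor 2) at 1.21 and SSB2 (a ribosome-bound chaperone) at 1.01.

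Spt5 had an excess of 0.57 over all intron genes and 0.06, at percentile 89.3, without the ribosomal protein group. In this column the histone genes had a median of 2.24, glycolytic genes 1.96 and the aldolase gene FBA1 alone 3.05. RNA polymerase II showed medians of 2.26 and 1.41 for the same lists. For the polymerase, intron genes stood 0.63 above unmatched intronless genes, and 0.20 without the ribosomal protein group. Quantile normalised these were 0.31 and 0.10, and for spans not a multiple of 3 the latter was 0.05, inside the range of random lists at percentile 73.6. Matched on Spt5 instead, the polymerase excess was -0.05 at percentile 28.8. On its own, the excess of Spt5 without matching was 0.86, and 0.15 outside the ribosomal protein group. Its matched excess over all intron genes was 0.32 after quantile normalisation and 0.35 for spans not a multiple of 3.

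Single genes were counted as well. Prp40 placed 124 of 211 intron genes above the 99th percentile of its intronless genes, Lea1 105, BBP and Prp11 94 each, Prp5 93, Mud2 43 and Prp19 39. The count was 11 for Prp2, 9 for Spt5, 6 for Brr2 and 2 for RNA polymerase II. At the 95th percentile the count was 106 for Mud2, 100 for Prp19 and 97 for Spt5, and 69, 34 and 21 for Prp2, Brr2 and RNA polymerase II. With the Mud2 sign turned its counts would be 0 and 1. With values at the limit of the scale left out, single highest values often fell on intronless genes. LIN1 (a U5 snRNP-associated protein) reached 3.88 and KAR1 3.84 for Mud2, LAA1 3.27 and ARG7 3.16 for Lea1, SPL2 2.94 for Prp11, and YDR034C-C 2.84 for BBP. The transcription activator gene GAL4 stood at 5.97 for Prp19, HAL9 at 5.92 and MDH2 at 5.83. Genes at the limit aside, the top genes for Prp2 were YDR042C at 5.31 and SCW10 at 4.86, and for Brr2 YOR012W at 6.59. For RNA polymerase II they were NAG1 at 5.73 and ASP1 at 5.63, and for Spt5 TOS1 at 4.69 and TRM44 at 4.50. Intron genes led for Prp5, with the respiratory chain gene QCR9 at 1.63, RPL2A at 1.61 and RPL19B at 1.59, and the snoRNA host RPS22B led for Mud2 at 4.15.

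Other fixed lists had their own profile across factors. Introns that carry a snoRNA lie in 8 measured genes, which had medians of 1.92 for Prp40, 1.84 for Lea1, 1.67 for Mud2, 1.13 for Prp11, 1.65 for Spt5 and 0.62 for Brr2. EFB1, 1 of these hosts, reached 3.01 for Lea1 and 2.96 for Prp19. Glycolytic genes, all intronless, had medians of 0.90 for Prp40, 0.88 for Prp5, 0.84 for Lea1, 1.17 for Prp2, 0.58 for Mud2, 0.54 for Prp11, 0.50 for Prp19 and 0.43 for BBP. Each of these lay above the range of random lists with similar polymerase values. A turned Mud2 column would have, relative to matched genes, values of -1.66 for snoRNA hosts, -0.56 for glycolytic genes and -1.12 for histone genes. Histone genes were above that range for Mud2 as deposited (1.15) and Prp2 (1.01), and HTA1 and HTB1 were below zero for RNA polymerase II (-0.34 and -0.30) where HHT2 had 2.85. Galactose genes, repressed in glucose, had a polymerase median of -0.88 and a Spt5 median of -0.57. Nucleotide synthesis genes were high for Prp11, at 0.27 (percentile 100) and for Prp40, at 0.22 (percentile 99.4).

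The relation of each factor to transcription was described by Spearman's rho with the RNA polymerase II column across genes, which are not independent replicates. Over intron genes rho was 0.84 for Spt5, 0.75 for Prp40 and Prp5, 0.71 for Prp11, 0.69 for Lea1, 0.67 for BBP, 0.59 for Brr2, 0.57 for Prp2, 0.55 for Mud2, 0.48 for Prp19 and 0.15 for Sub2. Mud2 would stand last, at -0.55, with the sign of its column turned. Across intronless genes it was 0.65 for Spt5, 0.45 for Prp40, 0.42 for Prp5 and 0.36 for Brr2, and from 0.22 for Lea1 down to 0.03 for Sub2 in the remaining factors as deposited, where Mud2 turned has -0.10. Among the 12 profiles, Prp40 shared its pattern over intron genes most closely with BBP and Prp5 (0.87 each). Mud2 and Brr2 reached 0.32 (-0.32 with the Mud2 sign turned). Pearson's r of Brr2 with the polymerase over intron genes was 0.22.

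A contrast of early with late factors was taken per gene as the mean of Prp40, BBP and Mud2 minus the mean of Brr2, Prp19 and Prp2, each centred on its intronless genes. Ribosomal protein intron genes had the larger contrast, with a median of 1.11 and 86 of 91 above zero. Their early and late medians were 1.87 and 0.72, against 0.57 and 0.14 for other intron genes. A difference of this kind can be larger where both values are larger, so it does not separate an early lean from a stronger signal. Other intron genes had 0.39, with 103 of 120 above zero, below the range of random intron lists (percentile 0.02). Among the genes at the early end were RPS22B at 1.97, RPS27B and RPL39 at 1.94, RPS17A at 1.74, RPS10B at 1.73, RPS13 at 1.69 and RPS23B and RPL18B at 1.66, together with QCR10 at 1.67, a subunit of respiratory complex III. At the other end stood QCR9, of the same complex, at -1.16, RPL16B at -0.60, RPS4B at -0.16, the coatomer gene SEC27 at -0.15, RPS4A at -0.12, RPL40B and the DNA repair gene MMS2 at -0.10, LSM2 at -0.05, ACT1 at -0.03 and RPL7A at 0.10. QCR9 owed its place to 3.08 for Brr2 and 2.02 for Prp19, against 1.51 for Prp40. RPL16B had 4.91 for Brr2.

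The contrast over all 211 intron genes was 0.64, above zero in 189 genes, and 0.97 without BBP. Meiotic intron genes had 0.24 at percentile 1.48 of random intron lists, below their range, 0.02 without Mud2 and 0.36 without BBP. Without Prp40 (0.28) or Prp2 (0.23) the meiotic value lay inside the range of random lists. The snoRNA hosts had 0.42 at percentile 17.8, 0.77 without BBP and 0.27 without Prp40. With the Mud2 sign turned the contrast becomes -0.53 for ribosomal protein intron genes, below the range of random intron lists, -0.08 for other intron genes, above that range at percentile 99.99, and -0.33 for all. The meiotic value is then -0.15 and inside the range, at percentile 82.1.

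**Figure D2:**
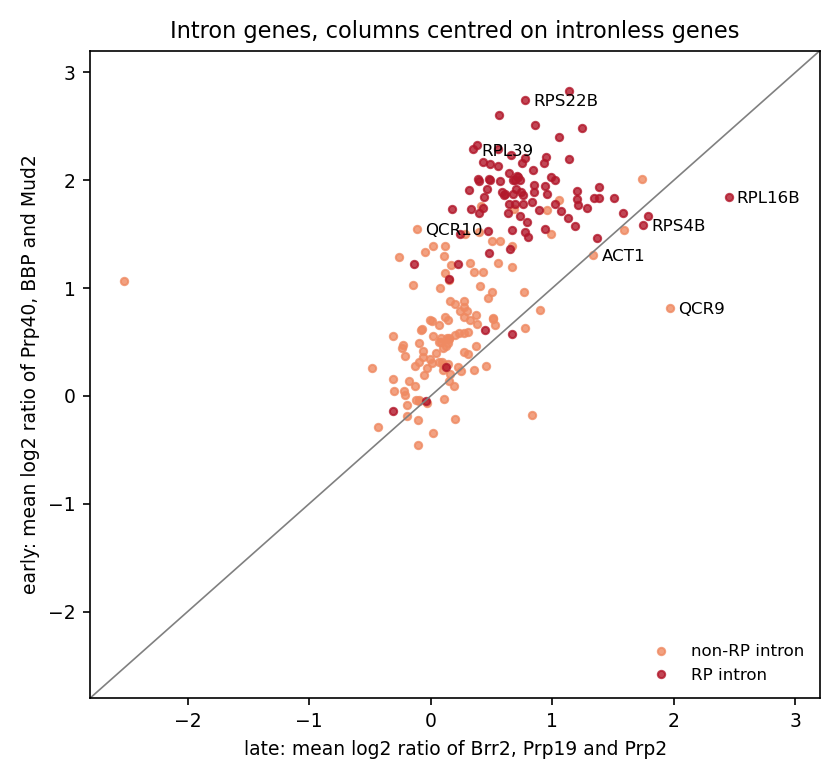
Mean log2 ratio of the early factors Prp40, BBP and Mud2 (vertical) against that of the late factors Brr2, Prp19 and Prp2 (horizontal) for each of 211 intron genes, with columns centred on intronless genes and a line where both are equal. The contrast is 1.97 for RPS22B, above the line, and -1.16 for QCR9, below it, and the lone point far to the left is GPI15, whose Prp2 value of -6.64 is at the limit of the scale.

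Deletion of the nuclear cap-binding complex was compared with the unperturbed Prp40 profile. Which of its genes was deleted is not given in the sources used here. CBC2, coding for the small subunit, stood at -2.37 in the deletion column and at -0.44 in the profile, while its lowest value in any other column was -0.76. STO1, coding for the large subunit, is itself an intron gene and stood at -0.01 against 0.98. CBC2 was picked after its values had been seen. Prp40 had an intron excess of 1.30 in the deletion and 1.28 in the profile, and rho between both columns over intron genes was 0.92. ACT1 stood at 2.66 in the deletion against 1.49, and differences of 0.78 for RPL30, 0.74 for RPL18B, 0.73 for UBC4 and 0.67 for BIG1 came next. The most negative differences were PSP2 at -2.40, the meiotic gene REC102 at -2.26, STO1 at -0.98, RPL2B at -0.95 and RPS13 at -0.88. Among intronless genes VPS13 and AUS1 lay at -3.14 and -3.12, and SPT6 and PAL1 at 1.63 and 1.22.

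Per gene, the median change of intron genes relative to matched intronless ones was -0.05 at percentile 0.96, with 127 of 211 below zero. Outside the ribosomal protein group it was 0.02 at percentile 74.3. Ribosomal protein genes with and without an intron had -0.16 and -0.14, a difference of -0.02 at percentile 24.8. Matching on the control column gave 0.03 in place of -0.05 and, outside the ribosomal protein group, 0.10 at percentile 99.9 in place of 0.02, and quantile normalisation gave -0.02 at percentile 12.7. Against the Prp40 column of the RNase experiment, which had a shorter fixation, the change was -0.35.

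RNase treatment of lightly fixed extracts asked whether the association of Prp40 and Mud2 with genes needs RNA. Without RNase, Prp40 had a median of 2.47 over ribosomal protein intron genes, and with RNase 0.18. Mud2 had 1.96 and 0.01 over the same group. RPL32 went from 3.99 to 0.38 for Prp40. For that factor MOB2 followed with a change of -3.60, RPL13B with -3.28, RPS25A with -3.27 and RPS29A with -3.17. For Mud2 the most negative changes were NMD2, of nonsense-mediated decay, at -4.41, RPL32 at -3.14, RPS26A at -2.84, RPS26B at -2.63 and the mRNA export gene YRA1 at -2.62. ACT1 stood at -2.12 for Prp40 and -1.81 for Mud2. Glycolytic genes, without introns, went from 1.01 to -0.03 for Prp40 and from 1.08 to -0.02 for Mud2, and all 16 were lower with RNase for both factors.

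Few intron genes were higher with RNase, led by BUD25 at 0.76, RPL43B at 0.37, RPS30A at 0.34, SPO1 at 0.31 and MEI4 at 0.27 for Prp40. RPS18A at 3.43, PSP2 at 1.08, HFM1 and RPS19A at 0.83 and BUD25 at 0.82 led for Mud2. Intronless extremes were ASP1 at -4.15 and AIM44 at 2.22 for Prp40, and BUB1 at -3.29 and CLB6 at 6.91 for Mud2. Histone genes changed by -1.11 for Mud2 (percentile 0.24) and had -0.81 for Prp40 (percentile 3.72). Translation factors and chaperones changed by -0.57 and -0.61. Amino acid synthesis genes changed by 0.07 for Prp40, at percentile 99.4.

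The intron excess was 1.67 without and 0.11 with RNase for Prp40, and 1.06 and 0.01 for Mud2. The change was -1.55 with 195 of 213 genes below zero for Prp40, and -0.96 with 184 of 213 for Mud2, each below every random list. Outside the ribosomal protein group it was -1.06 and -0.41, and with genes matched on the control column there -0.18 for Prp40 and -0.03 for Mud2, the latter inside the range of random lists at percentile 8.87. RNase narrowed the whole column, with a robust SD over genes of 0.23 without and 0.09 with RNase for Prp40, and 0.30 and 0.10 for Mud2. Over all intron genes matched on the control column the change was -0.45 for Prp40 and -0.23 for Mud2, and after quantile normalisation the Prp40 value was -0.48, with -0.44 outside the ribosomal protein group. Ribosomal protein genes with an intron fell further than those without, by -1.42 for Prp40 and -1.001 for Mud2. Quantile normalisation, which stretches the narrowed column, turned the Prp40 difference to 0.04.

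An impaired elongation factor, the spt5_194 mutant, was compared with a control strain, both with Prp40-3myc in medium without uracil. Histone genes had more Prp40 in the mutant, 1.17 against 0.28, with all 8 above the control and a median change of 0.85 at percentile 100. The change was 1.19 for HHF1, 1.14 for HHT2 and 1.08 for HHT1. Glycolytic genes also rose, by 0.35 at percentile 99.7, with PFK1 at 0.79 and GPM1 at 0.62. Ribosomal protein genes without an intron rose by 0.21 at percentile 99.3, while those with an intron had 0.04 at percentile 34.8. The difference between both groups of ribosomal protein genes was -0.17 at percentile 0.01, and -0.27 after quantile normalisation. The snoRNA hosts changed by -0.10, which is -0.19 relative to matched genes at percentile 2.38, with 4 of 8 below zero. These values hold for the mutant column as deposited. With its sign turned, the change relative to matched genes would be -1.13 for histone genes, -1.50 for glycolytic ones and -0.92 for ribosomal protein genes without an intron, in place of 0.76, 0.26 and 0.13, and the difference between ribosomal protein groups would be 0.20.

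Single intron genes with lower Prp40 in spt5_194 were RPS18A at -4.32, UBC5 at -4.25, REC102 at -2.00, the vesicle coat GTPase gene SAR1 at -1.32 and RPL31B at -0.80. Higher were RPL33A at 1.02, IMD4 at 0.61, RPS19A at 0.55, and RPL42B and DTD1 at 0.43. The protease gene YPS7 at -7.43 and the choline transporter gene HNM1 at -6.75 were the lowest intronless genes, and YDR034C-C was highest at 4.50. The same control column served for 6-azauracil. REC102, SAR1, RPL33A, RPS19A and YDR034C-C lay at the same end of both changes. Their control values were 1.47, 1.18, -0.51, -0.88 and -4.63, in that order. For these genes a response to mutant or drug cannot be told from an unusual control value. The change of intron excess was -0.02 at percentile 3.61, with 100 of 213 genes below zero, and -0.03 at percentile 4.97 outside the ribosomal protein group. Matching on the control column turned these to 0.06 at percentile 99.9 and 0.01 at percentile 62.6. A turned sign of the mutant column would give -0.33 and -0.06. The control column itself had an intron excess of 0.22, and 0.05 outside the ribosomal protein group. Its ribosomal protein genes with and without an intron differed by 0.02 (percentile 65.6). Little Prp40 particular to introns was there to be lost, so a small change does not show that it was kept.

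6-azauracil, a drug that depletes nucleotides and slows elongation, was added at 80 µg/ml for 30 min to the Prp40 control strain. With the drug column as deposited, Prp40 fell on ribosomal protein genes and rose on glycolytic ones. The median change was -0.56 over the 91 ribosomal protein genes with an intron, 88 of them below zero, and -0.25 over the 40 without one, 31 of them below zero. Glycolytic genes rose by 0.41 at percentile 98.9, with ADH1 at 0.69 and CDC19, pyruvate kinase, at 0.73. With the sign of the drug column turned the glycolytic change would be -2.14. The snoRNA hosts fell by 0.50 at percentile 0.01, with RPS22B at -0.99 and RPL7A at -0.95. The change of the hosts relative to matched genes would be -0.51 with the sign of the drug column turned, inside the range of random lists at percentile 3.89, where it is -0.65 as deposited. RPS13 went from 1.35 to 0.14. Other changes at that end were -1.49 for REC102, -1.17 for RPS27B, and -1.08 for RPL39 and SAR1. RPS19A stood highest at 0.92, YRA1 went from 1.21 to 1.70, and SRB2 had 0.45, RPL33A 0.44 and USV1 0.43. REC102, SAR1, RPS19A and RPL33A lay at the same ends in spt5_194, against the same control column. Among intronless genes YRF1-8 and MRPL15 lay at -4.76 and -4.62, and SPT6, a histone chaperone of elongation, at 5.96. Nucleotide synthesis genes, several of which respond to the drug, had a median change of -0.06 at percentile 12.3, with IMD3 at 0.86 and IMD2 at 0.47.

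Intron excess went from 0.22 to -0.12, and the change per gene was -0.43 at percentile 0 with 159 of 213 below zero. It was -0.12 at percentile 0.03 outside the ribosomal protein group, where 71 of 122 genes lay below zero, and -0.07 there when matched on the control column. The changes of ribosomal protein genes with and without an intron differed by -0.31 at percentile 0, while these groups differed by 0.02 (percentile 65.6) in the control column and by -0.34 in the drug column. With the sign of the drug column turned, the changes would differ by 0.36, and the change of intron excess would be -0.11, or -0.02 at percentile 34.3 outside the ribosomal protein group. Heat shock genes stood at 0.46 under the drug and 0.16 in the control, a change of 0.28 at percentile 96.3.

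**Figure D3:**
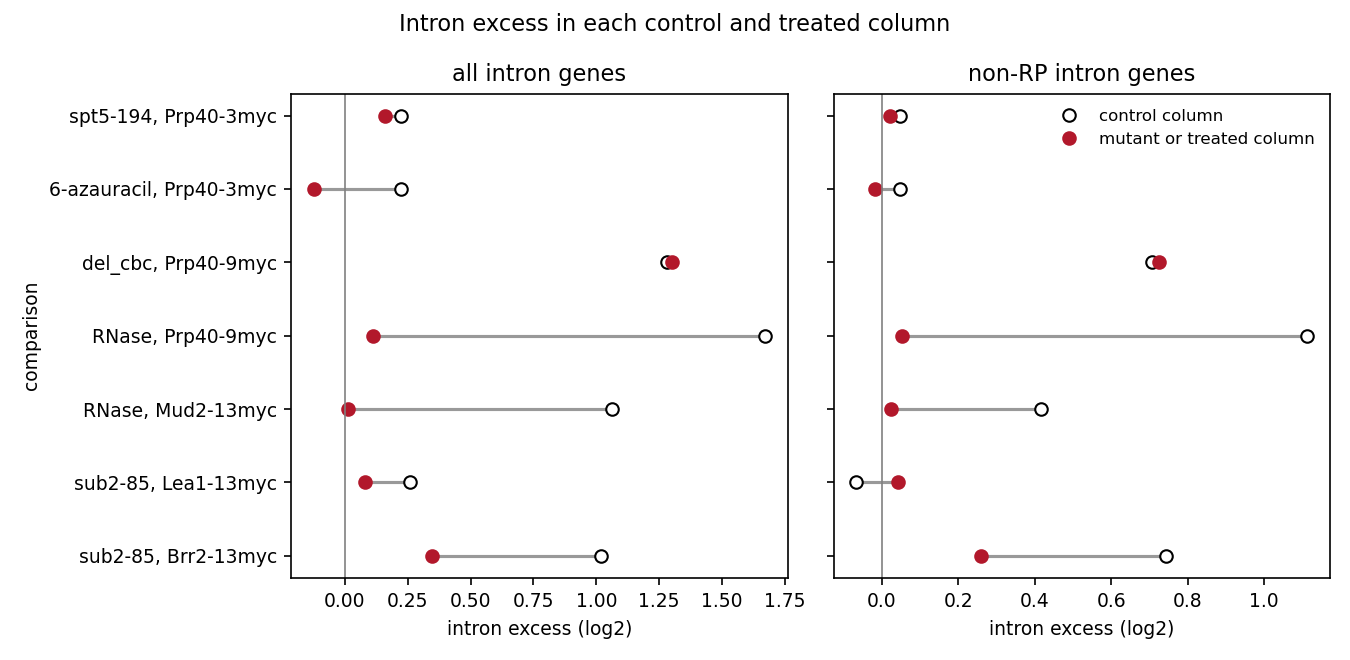
Intron excess (horizontal, log2) in the control column (open circles) and in the mutant or treated column (filled circles) for 7 comparisons (vertical), for all intron genes on the left and those outside the ribosomal protein (RP) group on the right. RNase moves Prp40 from 1.67 to 0.11 while the cap-binding complex deletion leaves it at 1.30 against 1.28.

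Loss of Sub2 function was studied with the heat-sensitive sub2-85 allele against SUB2 wild type, both held at 37°C for 30 min, with Lea1 and Brr2 tagged. Brr2 fell on ribosomal protein intron genes from 1.48 to 0.50, with 90 of 91 lower in the mutant and a median change of -0.995. The most negative changes were RPS9A at -2.19, the meiotic helicase gene HFM1 at -1.90, RPL2A at -1.83 and RPL20A at -1.79, and RPL39 went from 1.83 to -0.05. Ribosomal protein genes without an intron changed by -0.40, so that the difference was -0.60, and -0.35 after quantile normalisation. The snoRNA hosts fell by 0.94 in all 8 genes, glycolytic genes by 0.35 at percentile 1.46. Higher in the mutant were NMD2 at 2.47, BIG1 at 1.66, PSP2 at 1.46, BET4 at 0.77 and HNT2 at 0.63. ADE3 at -6.19, SEC1 at -5.85, VSB1 at 6.41 and URB2 at 6.19 were the intronless extremes.

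Lea1 had smaller values at 37°C from the start. Over ribosomal protein intron genes it fell from 0.74 to 0.16, with 88 of 91 lower, and over intronless ones by 0.45. The whole Lea1 column was narrower in the mutant, with a robust SD over genes of 0.12 against 0.19 in wild type. For Brr2 the robust SD was 0.37 against 0.25. The Lea1 fall thus cannot be told from a weaker signal on all genes. RPS26B went from 1.20 to 0.06 and RPS29A from 1.09 to -0.06, followed by RPL2A at -1.06, RPL14A at -1.02 and RPL37A at -1.01. Glycolytic genes changed by -0.22 at percentile 1.04, and snoRNA hosts by -0.57 in all 8 genes. If the sign of the wild-type column is turned, the change relative to matched genes is 0.04 at percentile 65.4 for glycolytic genes and 0.89 for snoRNA hosts, in place of -0.16 and -0.51. At the upper end stood UBC5 at 2.31, GPI15 at 0.77, the transcription factor gene USV1 at 0.65, HFM1 at 0.56 (-1.14 after quantile normalisation) and QCR10 at 0.55. Intronless extremes were MRPS16 at -2.89, HUA1 at -2.78, CSN9 at 10.41 and TOS2 at 9.01.

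The intron excess of Brr2 was 1.02 in wild type and 0.35 in sub2-85, a change of -0.69 with 187 of 213 genes below zero, and -0.43 outside the ribosomal protein group. That of Lea1 was 0.26 and 0.08, a change of -0.17 with 133 of 213 below zero, but 0.09 at percentile 100 outside the ribosomal protein group, where 45 of 122 genes lay below zero. As a mean the latter was 0.06, at percentile 81.3. Matched on the control column the Brr2 change was -0.30 and the Lea1 change ended at 0.01, at percentile 61.9, with -0.15 and 0.05 outside the ribosomal protein group. For Lea1 the wild-type column is among those examined for a turned sign, which would give 0.34, with -0.02 outside the ribosomal protein group. Relative to matched genes, ribosomal protein genes with an intron would then have 0.83 in place of -0.55. The rank correlation of 0.63 between this column and the Lea1 profile over intron genes argues against a turned sign.

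Separate experiments on the same factor give a yardstick for these changes, with the culture and fixation differing between them. The intron excess of Prp40 was 1.28 in rich medium, 1.67 with short fixation and 0.22 with the other tag in medium without uracil. For Mud2 it was 1.76 in the profile and 1.06 with short fixation. At 37°C without histidine Lea1 had 0.26 against 1.08 in rich medium, and Brr2 1.02 against 0.10. Except with RNase, each change of intron excess above is smaller than the largest such difference for its factor, and those with the cap-binding complex deletion, spt5_194 and Lea1 in sub2-85 are smaller than each of these differences. For Mud2 this holds for the profile as deposited. With its sign turned the profile would have -1.76, and the Mud2 change with RNase would be smaller than that difference too.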

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

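The comparison of control spots was chosen only after the values were seen. In the sub2-85 experiment, the 2 tagged factors moved in opposite directions on intron genes outside the ribosomal protein group. Relative to matched intronless genes the change was 0.086 for Lea1 and -0.43 for Brr2, each outside the range of random lists. Matched on the control column these were 0.053 and -0.15, closer together. The difference between both factors was not tested, since each has 1 column per strain. The Lea1 column was narrower in sub2-85, where the excess in this group was 0.04, and narrowing alone moves a negative excess upwards. The Lea1 control had an excess of -0.07 in this group before any loss of Sub2. Its direction is not given: with its sign turned the Lea1 change would be -0.02 at percentile 25.3, so the opposite directions hold only for the column as deposited. The rank correlation of 0.63 between this column and the Lea1 profile over intron genes argues against a turned sign. As a mean, the Lea1 change was inside the range at percentile 81.3.

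A spot of Arabidopsis DNA, which belongs to no yeast gene and to no comparison, gave a signal above the highest buffer spot (0.54) in 11 of the 22 columns that have a value for it. It read 3.73 in the cap-binding complex deletion and 3.22 in the Prp40-3myc control, 2.03 in the Prp40 profile, 1.78 for Spt5 and 1.64 for Mud2 without RNase. Values of 1.49 for BBP, 1.27 for Prp40 without RNase, 1.26 for Prp5, 1.20 for Brr2, 0.98 under 6-azauracil and 0.96 for Brr2 in SUB2 wild type complete the set. The spot was below zero in 6 columns, down to -1.54 for Lea1 in SUB2 wild type.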

How the results depend on the processing

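Values at the limit left out, spans not a multiple of 3, turned signs, quantile normalised ribosomal protein differences and all alternatives for changes outside the ribosomal protein group were chosen after seeing the data. An intron list from an annotation was not run, since the gene table gives no exons. Direction and side of the range held in 109 of 118 alternatives for the intron excess, 100 of 106 outside the ribosomal protein group, 62 of 71 for ribosomal protein differences, 47 of 55 for changes, 32 of 39 for changes outside the ribosomal protein group, 38 of 45 for the contrast and 377 of 423 for lists, while all 55 correlations between factors over intron genes held with limit values left out. For the exceptions the cause was not tested. Matched on Spt5 the intron excess was -0.021 for Brr2, -0.022 for Sub2 and -0.052 for RNA polymerase II. With means it was 0.072 for Brr2 and -0.0097 for Sub2, and outside the ribosomal protein group 0.13 for Prp2 and 0.017 for Brr2. Without ribosomal protein genes Brr2 and Sub2 had -0.017 and Spt5 0.060. Unmatched, the other intron genes gave 0.013 for Brr2 and 0.15 for Spt5, and with spans not a multiple of 3 RNA polymerase II gave 0.047. The Mud2 sign turned gives -1.76 and -0.66, and contrasts of -0.53, -0.079, -0.15, -0.65 and -0.33 for ribosomal protein, other, meiotic, snoRNA host and all intron genes, where other intron genes are above the range of random intron lists at percentile 99.99. The meiotic contrast was 0.28 without Prp40 and 0.23 without Prp2. At the 95th percentile counts were 106 for Mud2, 69 for Prp2, 34 for Brr2, 100 for Prp19, 8 for Sub2, 97 for Spt5 and 21 for RNA polymerase II, and the last had 1 at the 99th without limit values. The Mud2 sign turned gives counts of 0 and 1, at the 99th and 95th percentile. Matched on the control column, changes were 0.055 for spt5_194, 0.031 for the cap-binding deletion and 0.0096 for Lea1 in sub2-85. Without ribosomal protein genes the latter 2 had 0.016 and 0.086. Quantile normalised, the deletion had -0.023 and the RNase ribosomal protein difference of Prp40 0.040, where the flat column is stretched. Turned signs gave -0.33 for spt5_194 and 0.34 for Lea1. Outside the ribosomal protein group, matching on the control column gave 0.0058 for spt5_194, 0.098 for the deletion and -0.031 for Mud2 with RNase, means gave -0.0064 for the deletion and 0.058 for Lea1, and turned signs -0.021 for 6-azauracil and for Lea1. Ribosomal protein differences with the sign turned were -1.59 for Mud2, 0.15 for spt5_194, 0.34 for 6-azauracil, 0.032 for Mud2 with RNase and -0.16 for Lea1 in SUB2 wild type, and their changes 0.20 for spt5_194, 0.36 for 6-azauracil and 0.16 for Lea1. List changes with the sign turned were, for spt5_194, -0.92 on intronless ribosomal protein genes, -1.50 on glycolytic and -1.13 on histone genes. For 6-azauracil they were -1.71 on glycolytic genes, -0.51 on snoRNA hosts, where percentile 3.89 is inside the range, and -0.021 on other intron genes, and 0.087 on meiotic genes for Mud2 with RNase. For Lea1 they were 0.67 and 0.83 on ribosomal protein genes without and with an intron, -0.025 on other intron genes, 0.89 on snoRNA hosts, 0.037 on glycolytic genes, 0.20 on translation factors and -0.13 on heat shock genes. Lists in single columns with the sign turned were, for the Mud2 profile, -0.71 and -2.33 on ribosomal protein genes without and with an intron, -0.66 on other intron genes, -0.55 on meiotic genes, -1.66 on snoRNA hosts, -0.56 on glycolytic and -1.12 on histone genes. For spt5_194 they were -0.56 and -0.46 on ribosomal protein genes without and with an intron, -0.54 on snoRNA hosts, -0.95 on glycolytic genes, -0.39 on translation factors, -0.995 on histones, -0.17 on nucleotide and 0.10 on amino acid genes. For 6-azauracil they were 0.22 on ribosomal protein intron genes, -1.06 on glycolytic genes, -0.39 on translation factors and -0.28 on heat shock genes. Mud2 with RNase had -0.023 on other intron genes and 0.079 on meiotic genes. Lea1 in SUB2 wild type had -0.55 and -0.70 on ribosomal protein genes without and with an intron, 0.070 on other intron genes, -0.75 on snoRNA hosts, -0.21 on translation factors and 0.13 on heat shock genes. Pearson correlations with the polymerase over all genes were 0.262 for BBP, 0.449 for Prp40, 0.424 for Prp5, 0.185 for Prp2, 0.428 for Brr2, 0.225 for Prp19 and 0.638 for Spt5. Over intron genes they were 0.563 for BBP, 0.657 for Prp40, 0.477 for Mud2, 0.586 for Lea1, 0.626 for Prp11, 0.680 for Prp5, 0.393 for Prp2, 0.223 for Brr2 and 0.710 for Spt5. Intronless genes gave 0.189 for BBP, 0.470 for Prp40, 0.114 for Prp11, 0.390 for Prp5, 0.157 for Prp2, 0.393 for Brr2, 0.191 for Prp19 and 0.627 for Spt5. The Mud2 sign turned gives -0.137, -0.550 and -0.096 over all, intron and intronless genes, and over intron genes -0.721 with BBP, -0.706 with Prp40, -0.570 with Lea1, -0.618 with Prp11, -0.569 with Prp5, -0.683 with Prp2, -0.321 with Brr2, -0.365 with Prp19, -0.065 with Sub2 and -0.694 with Spt5. Without limit values, snoRNA hosts of Brr2 had 0.31 above matched genes, heat shock genes -0.0025 for Prp19, 0.0023 for the Prp40 RNase change and 0.13 for Lea1 in sub2-85, and galactose genes 0.0027 for Spt5. Of 98 single-gene changes under quantile normalisation, 72 moved by more than the robust spread of intronless genes, and HFM1 for Lea1 in sub2-85 turned to -1.14.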

Other observations

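All tests of explanations in the last 3 paragraphs were chosen only after the result was seen, while the gene lists were fixed beforehand. Heat shock genes and amino acid synthesis genes were high for RNA polymerase II, with medians of 0.98 over 19 genes and 0.84 over 25. Among them were HSP82, a chaperone of signalling proteins, at 2.12, HSP12 at 1.85, HSP104 at 1.79, ARG1 at 1.88 and MET17 at 1.74. Spt5 had medians of 0.43 and 0.27 on these lists, at percentiles 35.6 and 11 among genes with similar polymerase values. HSP12 stood at -0.996 for Spt5. Histone genes, in comparison, had 2.26 for the polymerase and 2.24 for Spt5. Prp40 without RNase lay below its matched range on amino acid genes, at -0.10 (percentile 0.26).

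Meiotic intron genes had a Mud2 median of 0.32 in the profile (percentile 98.4) and -0.47 with short fixation (percentile 0.05). With the sign of the profile turned, its value relative to matched genes would be -0.55, on the same side as with short fixation. The rank correlation of 0.66 between both Mud2 columns over intron genes argues against a turned sign. MEI4, needed for meiotic recombination, stood at 2.25 in the profile and SPO1 at 1.48. At 37°C heat shock genes had 0.45 for Brr2 in wild type and in sub2-85, and -0.09 for Lea1 in wild type (percentile 1.90), which would be 0.13 above matched genes with the sign turned. The probe for SUB2 itself read -0.63 and -0.89 for Lea1 in wild type and sub2-85, and 0.26 and -0.56 for Brr2. Among probes absent from the gene table, YGL102C stood above the 99th percentile of intronless genes in 16 of 24 columns, with 2.61 for Prp40, and YJL188C in 12, with 1.97.

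Sub2 showed no intron excess and little relation to the other profiles. A constant shift of its values along the table is argued against: over 6283 shifts the highest rank correlation with Prp40, Spt5 or RNA polymerase II was 0.0583, and without a shift it was also 0.0583. Noise independent from probe to probe is argued against as well, since neighbouring genes had a rank correlation of 0.175 where random orders reached 0.0253. What the Sub2 column follows stays open, and a biological cause was not tested.

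Brr2 had no excess on intron genes outside the ribosomal protein group in rich medium and 0.74 at 37°C. Values at the limit of the scale are argued against, because without them the rich medium value was still at percentile 25.3. Glycolytic genes were higher in rich medium by a median of 0.29 (0.14 to 0.39 over resamplings of the 16 genes, not a spread between cultures). Transcription of these genes at 37°C was not analysed here, so this difference cannot exclude weaker enrichment on all genes in rich medium. Glycolytic genes have no introns, so they cannot tell whether enrichment at introns alone was weaker. Lea1 was lower at 37°C by -0.54 (-0.57 with the sign of its 37°C column turned). That column was low on glycolytic genes too, at 0.16 against 0.84 in rich medium. Lea1 therefore cannot decide whether a culture at 37°C raises the value of every factor. An effect of the culture on Brr2 alone or on every factor stays open as a possible explanation. So does weaker enrichment in rich medium, on all genes or at introns alone, or a difference between separate experiments.

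With 6-azauracil Prp40 was lower on ribosomal protein intron genes, by -0.67 relative to matched genes, or -0.19 with the sign of the drug column turned. An equal fall of all ribosomal protein genes is argued against by the difference of -0.31 between those with and without an intron, which is 0.36 with the sign of the drug column turned. In the column as deposited, glycolytic genes rose by 0.41 (0.25 to 0.56 over resamplings of the 16 genes, not a spread between cultures). Transcription of these genes under the drug was not analysed here, so this rise cannot exclude weaker enrichment on all genes in the drug column. Glycolytic genes have no introns, so they cannot tell whether enrichment at introns alone was weaker. With the sign turned their change would be -2.14, but their median of 1.345 under the drug against 0.79 in the control is larger in size with either sign. In the control column ribosomal protein genes with and without an intron differed by only 0.02 (percentile 65.6), against -0.34 in the drug column as deposited. The control thus showed no Prp40 particular to these introns that could be lost, and an effect on early recruitment there was not shown. RNA polymerase II had a difference of -0.29 in its own profile. Under the drug it was not analysed here, and a change in transcription of intron genes stays open.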
